A study of Mus musculus with 6 samples.

How the data were processed

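The deposited files hold UMI counts per gene and cell barcode, made with Cell Ranger 6.1.1 per the file headers and aligned to mm10 per the submitters' processing notes, and no normalization had been applied to them. Their barcodes were already limited to those with at least 500 UMIs. The submitters' notes also name Seurat, but no file holds its output. The libraries are 3 controls (floxed Cldn5 without Cre) and 3 Cldn5 iECKO samples (with Cdh5-creERT2), per the labels, from brain microvessels taken after tamoxifen by gavage on 3 days. The transgene feature for the YFP reporter had 0 UMIs in every library, so it could not mark recombined cells. Of 32286 feature identifiers, 32158 were found in the reference annotation, which gave the coordinates on GRCm38.

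Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial counts. Scrublet's own threshold called almost no doublets, so the highest scores were removed at 0.8% per 1000 barcodes. Cells were clustered with scanpy 1.11.5 on 2000 variable genes, 40 principal components and 20 neighbours (Leiden resolution 1.0, leidenalg 0.10.2), with Cldn5 left out of clustering and naming. Clusters were named by fixed markers: at least 3 markers of a class had to be detected in at least 25% of cells. Barcodes with a large part of the markers of another class were removed as mixed. Markers of erythrocytes and of related classes, such as smooth muscle for pericytes, were not counted in this. Endothelial cells were clustered again (30 components, resolution 0.6) to name arterial, capillary and venous subclusters. Leading genes of a cluster are the 10 with the largest ratio to other cells after adding 5 CPM, above a floor of 50 CPM (a lower floor within endothelial cells). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, and R 4.3.3.

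Counts were summed per library and class, for libraries with at least 20 cells of the class. Groups were compared with edgeR 4.0.16 (robust quasi-likelihood, TMM factors, filterByExpr) at a Benjamini-Hochberg adjusted p under 0.05, two-sided, without pairing. Counts of changed genes leave out Cldn5. With no change at all, a share of 0.05 of the genes tested would have an unadjusted p under 0.05. CPM carry TMM factors, except those of Xist and Ttr, which like the Gm42418 percentages are shares of the raw endothelial sums. DESeq2 1.42.0, RLE factors, no filter on low counts, equal numbers of cells (1869 endothelial cells, 39 pericytes and 36 microglia per library), stricter cell filters (2000 UMIs, 5% mitochondrial counts), doublets kept, a marker gate for endothelial cells (4 own markers, under 2 of others), genes of free RNA left out (10 times higher in another class), each library left out in turn and the replicate number as a block were the alternatives. Cells called Cldn5-detected had at least 2 Cldn5 UMIs and undetected cells 0, among cells with at least 2000 UMIs, with a limit of 4000 UMIs and a gate of 0 or 1 against at least 5 Cldn5 UMIs as alternatives. Contrasts within iECKO libraries and between zones used the library as a block. The share of cells without a Cldn5 UMI was taken after thinning each cell to 2000 UMIs (1000 and 4000 as alternatives), with exact Clopper-Pearson 95% intervals and a two-sided exact permutation test between libraries; the intervals cover counting error only.

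Gene lists were tested with limma 3.58.1 (camera on voom values with a preset correlation, 41 tests adjusted together), and again with an estimated correlation and with fry. Lists of astrocyte genes could not be tested, since no cluster was named astrocyte. The lists, classes, tests and alternatives were fixed before the data were examined, except those said to be chosen after seeing the data. The genes named were set by a rule: Cldn5 in every library; in endothelial cells the 12 largest changes each way among genes past the threshold, with a mean log2 CPM of at least 5 and every iECKO library on the same side of every control; in other classes and in the contrast within iECKO libraries the 5 largest each way; and list members past the threshold, at most 4 per list. Predicted and sex-linked genes were counted and not named by it. Without pairing the rule names no endothelial gene, so it was also applied to the fit with the replicate block.

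Whether the replicate numbers pair the libraries was checked on the endothelial sums. Libraries with the same number had deviations from their group means that correlated across 13229 genes, which are not independent, with r of 0.424, 0.501 and 0.472. All other pairs of a control and an iECKO library were negative, which centring on group means favours once these are positive. Without sex-linked and ribosomal RNA-linked genes the same-number values were 0.407, 0.434 and 0.453. The counts with and without the block had been seen before these correlations were computed. In simulated data with known changes, the endothelial test recovered 4.5%, 56.7% and 90.9% of changes of 1.5-fold, 2-fold and 4-fold. These were 3, 38 and 60 genes, and 14 unchanged genes were called beside them. With the block the endothelial test recovered 44.8%, 76.1% and 95.5%, or 30, 51 and 63 genes, and 24 unchanged genes were called. In both endothelial fits false calls made up a larger share of all calls than the adjusted p threshold allows. The pericyte, smooth muscle and microglia tests recovered 35.8%, 32.8% and 29.9% of 2-fold changes, with 3, 5 and 7 unchanged genes called. The list test called a simulated list of 1.5-fold changes and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other. The endothelial activation and actin lists had estimated correlations of 0.453 and 0.699, so the simulation does not cover false calls in lists like these.

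Left out were clusters without a class, among them erythrocyte-like, choroid plexus-like and mixed ones, the lymphocytes of iECKO 2 (7 cells), and 26.9% to 69.8% of the pericyte barcodes of a library, which carried markers of other classes. A subcluster led by smooth muscle genes, with 41 of its 42 cells from iECKO 1, was given no zone. The stricter cell filter left too few pericytes to test. Single results on withheld items are not reported here.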

Results

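Brain microvessels of tamoxifen-treated mice were captured with magnetic beads carrying an antibody against PECAM1, an adhesion protein of endothelial cells, and their cells were profiled by droplet single-cell RNA-seq with the 3′ chemistry v3.1 of 10x Genomics. All mice carried floxed alleles of Cldn5, which encodes claudin-5, a strand-forming protein of the tight junctions of the blood-brain barrier. The Cldn5 iECKO mice also carried Cdh5-creERT2, a tamoxifen-inducible recombinase under the promoter of an endothelial cadherin, and the controls did not. There were 3 control and 3 Cldn5 iECKO libraries. The control libraries held 4049 to 6684 barcodes and 29721428 to 31638780 UMIs, and the iECKO libraries 2714 to 7420 barcodes and 15727366 to 49350802 UMIs. Of the cells kept, 3115 to 4768 per control library and 1869 to 4663 per iECKO library were used as endothelial cells, with medians of 3656 to 4827 and 4189 to 5733 UMIs. The median mitochondrial percentage of the cells kept was 3.59, 3.59 and 3.28 in control 1 to 3 and 4.04, 4.28 and 4.58 in iECKO 1 to 3, and the filters passed 93.9%, 85.5% and 95.8% of the control and 90.9%, 81.3% and 92.7% of the iECKO barcodes. Of the endothelial barcodes of iECKO 1, 7.63% were removed for markers of other classes, against 0.38% to 1.58% in the other libraries. Replicate 2 of each group came from female tissue: Xist, the RNA that silences an X chromosome, stood at 809 and 908 CPM in its endothelial cells and at 0.3 CPM or less in the other libraries. Gm42418, a predicted gene that collects ribosomal RNA reads, took 7.90%, 18.8% and 2.71% of the endothelial counts in control 1 to 3 and 7.90%, 16.1% and 2.96% in iECKO 1 to 3. The labels do not say whether a library is 1 animal, so the p-values measure the spread between these libraries.

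The targeted gene was examined first. Cldn5 (ENSMUSG00000041378) lies on chromosome 16 from 18776847 to 18778262 on the plus strand of GRCm38 and has a single exon, with its coding sequence from 18776996 to 18777649 between both untranslated parts. In endothelial cells it stood at 4775, 4269 and 4874 CPM in control 1 to 3 and at 2846, 2292 and 2848 CPM in iECKO 1 to 3, or 4640 ± 324 against 2660 ± 320 CPM (SD, n = 3). The log2 difference was -0.80 ± 0.20 (SE), lower in 3 of 3 pairs of libraries with the same number. It did not pass edgeR's quasi-likelihood test without pairing (adjusted p = 0.28) and passed with the replicate number as a block (-0.80 ± 0.09, adjusted p = 0.00628) and with DESeq2 (-0.81, adjusted p = 0.000145). The labels do not say which part of the gene is floxed. A 3′ tag that lies outside the deleted part would still be counted, so the Cldn5 counts report transcript and cannot by themselves check the deletion.

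How many endothelial cells had lost the transcript was asked at a fixed depth, because the series title calls the deletion mosaic. At 2000 UMIs per cell, 4.29%, 5.51% and 2.90% of the endothelial cells of control 1 to 3 held no Cldn5 UMI. In iECKO 1 to 3 the shares were 23.7%, 21.5% and 19.9% (4.23% ± 1.31 against 21.7% ± 1.92, SD, n = 3). The difference of 17.5 percentage points had a two-sided exact permutation p of 0.1, the smallest that 3 libraries against 3 allow, and each iECKO library lay above each control. Microglia, which do not make claudin-5, gave the background of free RNA: 88.7% ± 6.2 and 88.4% ± 6.92 of those not removed as mixed held no Cldn5 UMI at the same depth. Median depths before thinning were 3624 to 5089 and 3336 to 5745 UMIs in microglia of control and iECKO libraries, against 4014 to 5117 and 4770 to 5921 UMIs in the endothelial cells. Without thinning, the endothelial shares were 3.55% ± 1.06 and 17.2% ± 2.09. Among cells with at least 2 Cldn5 UMIs at this depth, the median was 9, 8 and 10 in the controls and 6, 5 and 7 in the iECKO libraries. Shallower cells, 214 to 754 per control and 127 to 583 per iECKO library, were left out.

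**Figure D1:**
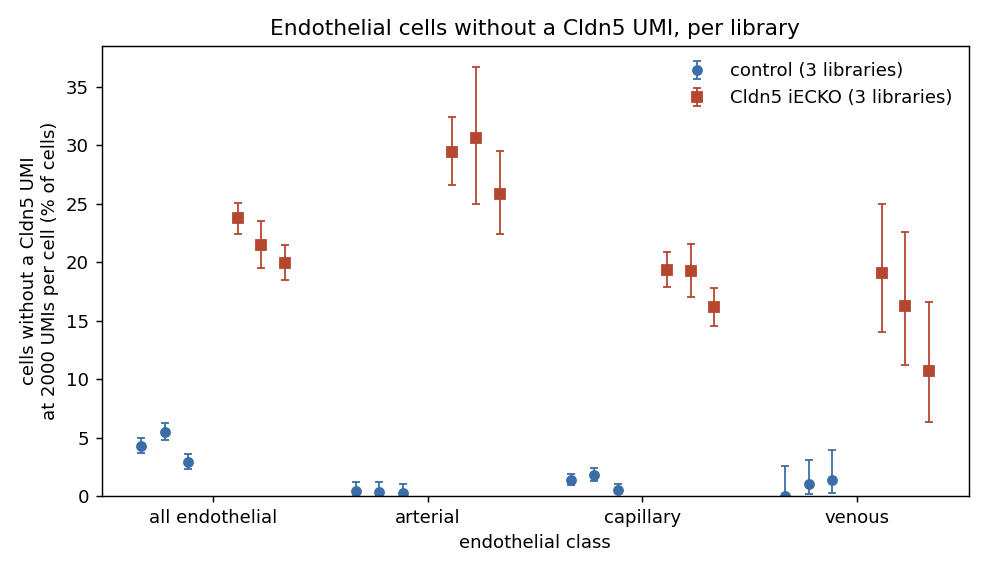
Endothelial cells without a Cldn5 UMI after thinning to 2000 UMIs per cell, as a percentage of the cells of each class (y axis), for all endothelial cells and for arterial, capillary and venous cells (x axis). Circles are the 3 control and squares the 3 Cldn5 iECKO libraries, with exact 95% binomial intervals that cover counting error only. Over all endothelial cells the controls lie between 2.90% and 5.51% and the iECKO libraries between 19.9% and 23.7%.

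The loss was seen along the whole vascular tree. Arterial cells without a Cldn5 UMI made up 0.373% ± 0.0737 of control and 28.6% ± 2.48 of iECKO arterial cells. For capillary cells the shares were 1.26% ± 0.627 and 18.2% ± 1.81, and for venous cells 0.81% ± 0.716 and 15.4% ± 4.27 (SD, n = 3, exact permutation p = 0.1 in each class, the smallest possible). In control 1, 0 of 143 venous cells lacked a Cldn5 UMI, a share whose exact 95% upper bound was 2.55%. Within the iECKO libraries the arterial share exceeded the capillary one by 10.4 ± 0.887 percentage points and the venous one by 13.3 ± 2.55. The capillary share exceeded the venous one by 2.89 ± 2.59. Each difference was seen in 3 of 3 libraries (two-sided exact p = 0.25, the smallest that 3 libraries allow). In iECKO 1 the capillary and venous shares were 19.35% and 19.07%, with overlapping 95% intervals (17.88% to 20.89% and 14.05% to 24.97%). Cldn5 itself was -1.27 ± 0.23 in arterial, -0.69 ± 0.21 in capillary and -0.84 ± 0.24 in venous cells on the log2 scale. With the replicate block it fell in each of these classes, with changes of -1.28 ± 0.13 (adjusted p = 6.79e-07), -0.70 ± 0.11 (adjusted p = 0.018) and -0.85 ± 0.10 (adjusted p = 0.0035), listed in the same order. The venous estimate was larger in size than the capillary one in both fits, although the venous share was lower. The interaction test did not separate the zones, with a further -0.58 ± 0.17 in arterial (adjusted p = 0.319) and -0.16 ± 0.17 in venous against capillary cells (adjusted p = 0.77).

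**Figure D2:**
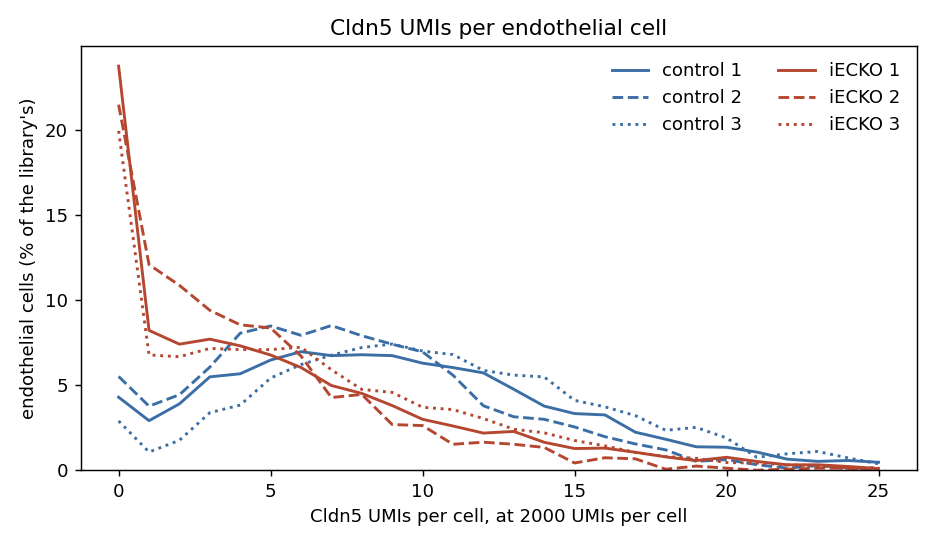
Endothelial cells of each library (y axis, % of the library's cells thinned to 2000 UMIs) by their number of Cldn5 UMIs (x axis); blue lines are control 1 to 3 and red lines iECKO 1 to 3. The iECKO curves have a peak at 0 UMIs, and the cells with at least 2 Cldn5 UMIs have medians of 5 to 7 against 8 to 10 in the controls.

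Whether endothelial cells changed beyond Cldn5 was tested on the counts summed per library. Prnd, which encodes the prion-like protein doppel, was the gene past the threshold without pairing. It rose from 2.23 ± 0.241 to 16.8 ± 5.92 CPM (SD, n = 3; log2 2.91 ± 0.28, adjusted p = 0.0271), in 3 of 3 pairs. With the replicate block 154 genes rose and 63 fell. Among these, Ccnd1, which encodes cyclin D1 of the G1 phase (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925), rose from 93.4 ± 17.9 to 268 ± 43.2 CPM (1.53 ± 0.12, adjusted p = 0.00229). The ion cotransporter gene Slc12a2 (1.43 ± 0.17), the homeobox gene Meox1 (1.37 ± 0.12) and the actin-capping gene Capg (1.22 ± 0.17) rose as well. So did the small GTPase gene Rhoc (1.20 ± 0.12), the NF-kappaB subunit gene Nfkb2 (1.14 ± 0.16) and Tgfb1 (1.12 ± 0.15). Their adjusted p lay between 0.00261 and 0.0423. Pglyrp1, a peptidoglycan receptor, went from 779 ± 301 to 1640 ± 687 CPM (1.07 ± 0.09, adjusted p = 0.00229). Cx3cl1, the chemokine fractalkine, went from 72.2 ± 3.6 to 155 ± 53.4 CPM (1.05 ± 0.15, adjusted p = 0.0343). Cd93, an endothelial lectin-like receptor, went from 463 ± 12.7 to 948 ± 256 CPM (1.00 ± 0.14, adjusted p = 0.0256). Gimap6 stood at 1.05 ± 0.12 and the cytokine receptor gene Crlf2 at 1.05 ± 0.14.

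Genes that fell in endothelial cells with the replicate block and met the naming rule had smaller changes than those that rose and met it. Ltbp4, whose product stores latent TGF-beta in the matrix, fell from 739 ± 24.8 to 463 ± 54 CPM (-0.68 ± 0.10, adjusted p = 0.0212). The semaphorin gene Sema3c fell from 611 ± 37.1 to 384 ± 71.1 CPM (-0.68 ± 0.10, adjusted p = 0.0202). Cst3, which encodes the protease inhibitor cystatin C, fell from 1270 ± 271 to 833 ± 96.4 CPM (-0.58 ± 0.11, adjusted p = 0.042). Plscr2 (-0.78 ± 0.13), the stress gene Gadd45g (-0.74 ± 0.11), the planar polarity gene Prickle1 (-0.74 ± 0.11) and the endothelin gene Edn3 (-0.67 ± 0.12) fell too. So did Crispld1 (-0.64 ± 0.08), the epoxide hydrolase gene Ephx1 (-0.62 ± 0.10), the fibulin gene Fbln2 (-0.61 ± 0.08), Syt7 (-0.59 ± 0.10) and the BMP target gene Id2 (-0.57 ± 0.08). Their adjusted p lay between 0.0115 and 0.0467. For these 24 genes and their paired values the rule fixed beforehand was applied to the fit with the block, a choice made after the values were seen. Without pairing, edgeR called 1 gene higher and 0 lower, with 960 of 13229 genes at an unadjusted p under 0.05, and DESeq2 called 133 and 30. Without iECKO 3 the unpaired counts were 102 higher and 12 lower, and without any other single library both were 0.

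**Figure D3:**
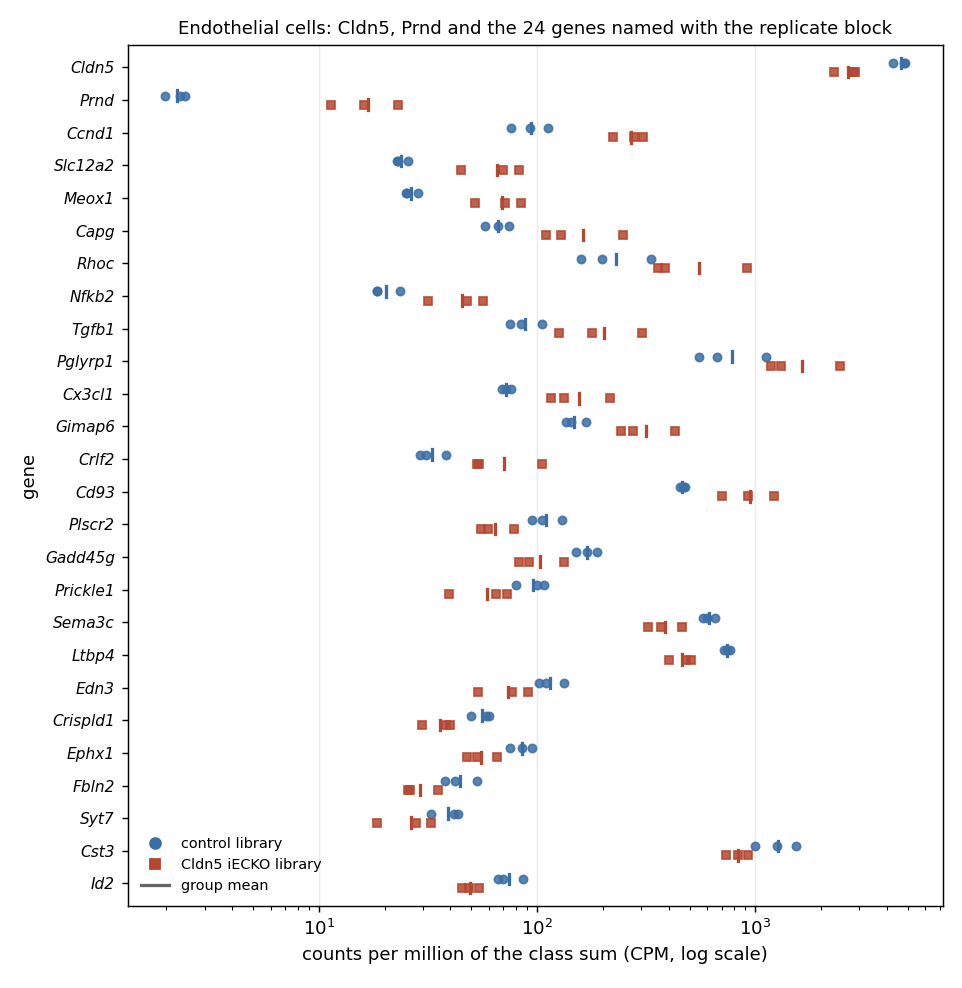
CPM in endothelial cells (x axis, log scale) for Cldn5, Prnd and the 24 genes named with the replicate block (y axis). Circles are control and squares Cldn5 iECKO libraries, 3 each, and vertical bars the group means. In each named gene the iECKO libraries lie on 1 side of all controls, as for Ccnd1 with means of 93.4 and 268 CPM.

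Gene lists fixed beforehand were then compared between the groups. The list of endothelial activation and leukocyte adhesion genes rose, with the largest median of the endothelial lists that passed (0.73, 26 genes, 23 of them positive; limma camera adjusted p = 3.82e-10, adjusted p = 0.395 with an estimated correlation). The selectin gene Sele (2.90 ± 0.29, from 0.415 to 3.17 CPM), the NF-kappaB gene Relb (0.92 ± 0.12) and Cx3cl1 passed over all genes with the block. Without it 0 passed in edgeR, and 5 of the members passed when adjusted over the list alone (4 with the block). Icam1, a leukocyte adhesion receptor, stood at 76.7 and 117 CPM (0.61 ± 0.29, adjusted p = 0.724). The basement membrane, matrix and integrin list rose as well (median 0.42, 28 genes, adjusted p = 6.43e-06; adjusted p = 0.395 with an estimated correlation). Over all genes 3 members rose and 1 fell with the block and 0 without it, and adjusted over the list alone 9 rose and 1 fell. The nidogen gene Nid1 (1.00 ± 0.12), the laminin gene Lamc1 (0.85 ± 0.14) and the integrin gene Itga6 (0.65 ± 0.11) rose and the collagen gene Col15a1 (-1.16 ± 0.18) fell with the block, with adjusted p of 0.0115 to 0.0356. Actin cytoskeleton genes rose (median 0.31, 24 of 28 positive, adjusted p = 8.84e-05; adjusted p = 0.544 with an estimated correlation), Rhoc and Capg passing over all genes with the block and 1 member adjusted over the list alone without it.

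Angiogenesis and tip cell genes rose (median 0.19, 20 of 27 positive, adjusted p = 0.000655; adjusted p = 0.395 with an estimated correlation), with 7 members higher and 1 lower adjusted over the list alone and 0 over all genes. With the block the semaphorin receptor gene Plxnd1 (0.71 ± 0.10, adjusted p = 0.0171), Cd34 (0.50 ± 0.09, adjusted p = 0.0313) and Flt4 (0.49 ± 0.10, adjusted p = 0.0467) rose over all genes. Angpt2, an antagonist of the receptor Tie2, was 2.45 ± 0.27 (adjusted p = 0.051) and Esm1, a tip cell gene, -1.74 ± 0.28 (adjusted p = 0.103). The hypoxia and glycolysis list rose by a median of 0.18 (14 of 18 positive, adjusted p = 0.0197; adjusted p = 0.552 with an estimated correlation). In edgeR 0 members passed over all genes with or without the block, and 0 adjusted over the list alone. With the block 4 passed over the list alone, the glycolytic genes Gapdh, Pgk1 and Pkm and the cytokine gene Mif. The haemostasis and fibrinolysis list had a median of 0.31 (adjusted p = 0.157) and was past the threshold with the block (adjusted p = 0.0295; adjusted p = 0.594 with an estimated correlation). In iECKO 1 most capillary cells lay in a subcluster led by Apln, Odc1, Adm and Kit and most arterial cells in one led by S100a6 and Ccn3. In the other libraries other capillary subclusters and a subcluster led by Gkn3 held more of them. The Apln-led subcluster held 0.61%, 0.59% and 0.58% of the endothelial cells of control 1 to 3 and 44.1%, 20.2% and 5.95% of those of iECKO 1 to 3. That led by S100a6 held 1.04%, 0.57% and 0.77% against 18.3%, 4.17% and 1.97%, so capillary and arterial cells of the groups lay in part in different subclusters. Angpt2 is also among the leading genes of the Apln-led subcluster.

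Barrier genes other than Cldn5 were asked after separately. No difference was detected for the junction proteins as a list (median 0.07, 11 of 18 positive, adjusted p = 0.397). Of the 18, 0 passed edgeR over all genes or adjusted over the list alone, with or without the block (960 genes in all had an unadjusted p under 0.05). Occludin (Ocln) was -0.13 ± 0.14, the scaffold gene Tjp1 -0.12 ± 0.20, the endothelial cadherin gene Cdh5 0.15 ± 0.16, Pecam1 0.24 ± 0.17 and the tricellular junction gene Marveld2 0.62 ± 0.20 (adjusted p = 0.451). Transporters of the blood-brain barrier fell slightly as a list (median -0.09, 17 of 26 negative, adjusted p = 0.0248; adjusted p = 0.429 with an estimated correlation). Without the block 0 members were called over all genes or adjusted over the list alone. With the block the monocarboxylate transporter gene Slc16a1 (-0.75 ± 0.13, from 653 to 395 CPM, adjusted p = 0.0423), the arginine transporter gene Slc7a1 (-0.50 ± 0.09, adjusted p = 0.0356) and the vitamin transporter gene Slc5a6 (-0.56 ± 0.11, adjusted p = 0.0467) fell. Slc7a3 (1.11 ± 0.18, adjusted p = 0.029) rose, with 9 lower and 1 higher adjusted over the list alone. The glucose transporter gene Slc2a1 stood at 1420 and 1640 CPM (0.21 ± 0.27), the efflux pump gene Abcb1a at 1430 and 1340 CPM (-0.09 ± 0.20) and the lipid transporter gene Mfsd2a at 253 and 231 CPM (-0.13 ± 0.19). The Wnt and beta-catenin list fell (median -0.13, 15 of 19 negative, adjusted p = 0.0197; adjusted p = 0.531 with an estimated correlation). Of its members 0 passed over all genes or adjusted over the list alone, with or without the block. Its target gene Axin2 was -0.34 ± 0.20, Lef1 -0.18 ± 0.16 and Apcdd1 -0.22 ± 0.32.

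Interferon-induced genes fell in endothelial cells (median -0.20, 21 of 25 negative, adjusted p = 0.000467; adjusted p = 0.531 with an estimated correlation). With the block Ifi27l2a (-0.51 ± 0.08, adjusted p = 0.0243) and Bst2, which encodes the antiviral protein tetherin (-0.53 ± 0.10, adjusted p = 0.0423), fell over all genes and adjusted over the list alone, 2 members in all. Without the block 0 did either. Immediate-early and dissociation stress genes fell (median -0.15, 20 of 27 negative, adjusted p = 0.00215; adjusted p = 0.453 with an estimated correlation), Gadd45g over all genes with the block and 3 members adjusted over the list alone. The caveolar and peripheral-type list (median -0.04, adjusted p = 0.145) and the unfolded protein response (0.12, adjusted p = 0.145) did not pass. Neither did TGF-beta and BMP signalling (median -0.19 but mean 0.07, test downward, adjusted p = 0.247), MHC class I presentation (0.00, adjusted p = 0.597), cell cycle genes (median 0.01, mean -0.04, adjusted p = 0.924) and sex-linked genes (adjusted p = 0.633). No list passed with an estimated correlation or with limma's fry in endothelial cells, where 0 of the 17 lists were called by either, against 9 by camera. Without control 2, camera called 5 lists, and without iECKO 1 it called 6. With 1 library left out, its largest adjusted p was 0.171 for actin, 0.0857 for interferon, 0.192 for immediate-early and 0.171 for Wnt genes. It was 0.879 for hypoxia and glycolysis genes and 0.0992 for transporters. The activation (8.45e-07), matrix (0.00091) and angiogenesis lists (0.0138) passed in every such fit.

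Each zone of the vascular tree was tested on its own next. In capillary cells Ccnd1 rose from 60.5 ± 6.25 to 277 ± 58.3 CPM (2.21 ± 0.20, adjusted p = 0.00915) and Meox1 from 19.1 ± 1.46 to 90.7 ± 28.7 CPM (2.26 ± 0.24, adjusted p = 0.0185). Prnd (2.91 ± 0.34) and the Ras-effector gene Rassf2 (2.26 ± 0.28) rose too. With the block 303 genes rose and 96 fell in capillary cells. The integrin gene Itga4 rose (1.57 ± 0.20, adjusted p = 0.0205). Edn1, the vasoconstrictor endothelin-1 (from 284 ± 58.7 to 100 ± 14.2 CPM, -1.48 ± 0.10, adjusted p = 0.000502), and the proteoglycan gene Spock2 (-0.89 ± 0.15, adjusted p = 0.0302) fell. In arterial cells Slc12a2 (1.43 ± 0.18, adjusted p = 0.0184), Nfkb2 (1.45 ± 0.21, adjusted p = 0.0444) and the T-box gene Tbx1 (1.13 ± 0.17, adjusted p = 0.046) rose. Enpp2, which encodes the lysophosphatidic acid-producing enzyme autotaxin, rose too (from 70 ± 4.62 to 168 ± 9.21 CPM, 1.26 ± 0.16, adjusted p = 0.0184). It is also a marker of choroid plexus epithelium. Ttr, a transcript of that epithelium, stood at 56.6, 222 and 2 CPM in the endothelial cells of control 1 to 3 and 98.6, 123.4 and 46.9 CPM in those of iECKO 1 to 3. With the block 205 arterial genes rose, Cx3cl1 among them (1.33 ± 0.13, adjusted p = 2.56e-06). Another 115 fell, such as the serine protease gene Htra1 (-1.14 ± 0.12) and the chemokine gene Cxcl12 (from 2920 ± 472 to 1600 ± 710 CPM, -0.95 ± 0.18, adjusted p = 0.0169). In venous cells 0 genes passed edgeR without the block (482 of 10414 at an unadjusted p under 0.05, 14 with DESeq2). With it 20 rose and 10 fell. Scgb3a1 (2.06 ± 0.18, adjusted p = 0.000331) and the matrix gene Igfbp7 (from 726 ± 149 to 1520 ± 695 CPM, 1.00 ± 0.14, adjusted p = 0.0132) rose, and the flow-responsive factor gene Klf2 fell (-0.63 ± 0.12, adjusted p = 0.0449).

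Without pairing, 4 capillary genes rose and 0 fell (1195 of 12356 at an unadjusted p under 0.05, 295 called by DESeq2), and 4 arterial genes rose and 0 fell (562 of 11139, and 29). Leaving out iECKO 3 raised these counts to 315 in capillary, 14 in arterial and 18 in venous cells. Capillary counts were 7 without iECKO 1, 2 without control 1, 1 without iECKO 2 and 0 without control 2 or control 3. Arterial counts were 0 without control 3 or iECKO 1, and venous counts 2 without control 3. Capillary counts with the Apln-led subcluster left out, an alternative chosen after seeing the data, were 0 (418 of 12235 at an unadjusted p under 0.05).

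The change itself differed between zones for some genes. Against the capillary change, with libraries as blocks, 51 genes had a higher and 130 a lower change in venous cells. The cytoskeletal and matrix genes Rhoc (-1.42 ± 0.22, adjusted p = 0.0165) and Nid2 (-1.67 ± 0.28, adjusted p = 0.00996) and the endosomal gene Litaf (-1.49 ± 0.28, adjusted p = 0.0213) had lower changes in venous cells. Cp, which encodes the ferroxidase ceruloplasmin (1.02 ± 0.13, adjusted p = 0.000855), the kinase gene Bmx (1.47 ± 0.34, adjusted p = 0.0444) and Ifitm1 (1.55 ± 0.35, adjusted p = 0.0367) had higher ones. Among the listed genes, the actin genes Actb (-0.49 ± 0.10, adjusted p = 0.0112) and Pfn1 (-0.62 ± 0.10, adjusted p = 0.00124) and the MHC class I genes H2-K1 (-0.56 ± 0.09, adjusted p = 0.00179) and H2-D1 (-0.48 ± 0.08, adjusted p = 0.00234) were lower. In arterial against capillary cells 1 gene had a higher and 12 a lower change. Apobec3 was higher (0.61 ± 0.12, adjusted p = 0.0162). The VEGF co-receptor gene Nrp1 (-0.90 ± 0.12, adjusted p = 0.00072), the Notch ligand gene Dll4 (-0.80 ± 0.13, adjusted p = 0.00686) and Igfbp3 (-1.58 ± 0.19, adjusted p = 0.00188) were lower. These genes were chosen after their values were seen, from those with a mean log2 CPM of at least 5. The venous counts ranged from 45 without iECKO 1 to 442 without iECKO 3, with 53, 71, 57 and 65 without control 1, control 2, control 3 and iECKO 2. The arterial ones ranged from 4 without control 1 to 182 without iECKO 3, with 8 without control 2 and 7 without iECKO 2. With the Apln-led subcluster counted as venous, an alternative chosen after seeing the data, the counts were 1621 and 0, and the directions of Rhoc (0.99), Nid2 (1.37), Litaf (0.092), Cp (-0.40) and Bmx (-0.11) reversed. The marker scores that named this subcluster were 0.43 for capillary and 0.41 for venous. Without the libraries as blocks both counts were 0 in edgeR (323 and 131 of 11794 genes at an unadjusted p under 0.05).

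Because not all endothelial cells of the iECKO libraries lacked the transcript, those that kept it could be set against control cells. Endothelial cells with at least 2 Cldn5 UMIs (1283 to 3072 per iECKO and 2815 to 3759 per control library, all with at least 2000 UMIs) differed from control cells of the same gate. Ccnd1 rose from 76.6 ± 14.7 to 262 ± 44 CPM (1.79 ± 0.20, adjusted p = 0.034) and Meox1 from 15.5 ± 1.35 to 63 ± 16.2 CPM (2.03 ± 0.20, adjusted p = 0.0323). The actin-bundling gene Fscn1 (3.54 ± 0.41, adjusted p = 0.0454), Prnd (2.74 ± 0.31), Rassf2 (2.24 ± 0.28) and the sulfotransferase gene Chst2 (1.47 ± 0.19) rose as well. Fscn1, a leading gene of the Apln-led subcluster, had an adjusted p of 0.108 with the block. Cldn5 in these cells was itself -0.64 ± 0.20 (blocked -0.64 ± 0.09, adjusted p = 0.0153). In all, 6 genes rose and 0 fell without pairing (984 of 13044 at an unadjusted p under 0.05, 136 and 26 with DESeq2), and 168 and 59 with the block. The total was 141 in both directions without iECKO 3, 2 without control 1 and 0 without any 1 of the other 4 libraries.

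Cells without a Cldn5 UMI (225 to 720 per iECKO library) were set against the same control cells. The genes that rose most were Col13a1 (5.17 ± 0.24, adjusted p = 5.2e-07), Rbp7 (5.05 ± 0.42), Gpihbp1 (4.44 ± 0.70), Cd300lg (4.33 ± 0.25) and Plvap. Plvap, which encodes the diaphragm protein of fenestrated endothelium, rose from 22.4 ± 1.72 to 525 ± 156 CPM (4.62 ± 0.25, adjusted p = 1.71e-06). All 5 are leading genes of an endothelial subcluster led by Plvap. That subcluster, which has little Cldn5 in the controls, made up 11.3% to 13.3% of the undetected cells of the iECKO libraries and 87.0% to 92.1% of those of the controls, so the gate selects it. Wnt5a (-2.54 ± 0.24, adjusted p = 0.000121) and the venous genes Slc38a5 (-2.00 ± 0.22, adjusted p = 0.000316) and Nr2f2 (blocked -1.74 ± 0.15, adjusted p = 4.93e-07) fell. So did the adhesion gene Flrt2 (-1.90 ± 0.24), the arterial gene Gkn3 (-2.12 ± 0.40; blocked adjusted p = 0.289) and Ndnf (-1.82 ± 0.33). In all 361 genes rose and 130 fell, 736 and 496 with the block; the total of 491 was 243 without iECKO 1, 217 without control 3, and 117 without the Plvap-led subcluster, an alternative chosen after seeing the data. Both comparisons share their controls: across 12260 genes, which are not independent replicates, their log2 fold changes correlated with r = 0.539 (Spearman 0.562). Simulated unchanged groups, which shared the controls and the iECKO libraries in the same way, gave 0.684 on average over 40 draws. The covariance was 0.12 where the simulated one averaged 0.067 and reached at most 0.079. They had 6 higher genes in common, where simulated groups gave 0.35 and independent lists 0.159. With the replicate block 122 higher and 36 lower genes were in common, where independent lists would share 8.98 and 2.32. The blocked fit was not simulated. The covariance and the higher genes in common thus exceeded what sharing controls and iECKO libraries gave in the draws. The correlations did not, nor did the lower genes in common without the block (0, where simulated groups gave 0.3). The draws took libraries of the same number as unrelated. With 3 controls no split was possible, so this excess rests on the spread assumed in the simulation.

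Within the iECKO libraries, undetected and detected cells of the same library were compared directly, with the library as a block. Over all endothelial cells 781 genes were higher and 763 lower in undetected cells (130 and 24 without the block, 384 and 268 with DESeq2). The largest differences upward were those of Cpxm2 (8.37 ± 1.04), Lrrc3b, Ces2e, Rbp7 and Ntf3, and downward those of the BMP antagonist gene Grem1 (-7.32 ± 1.73), the retinal dehydrogenase gene Aldh1a1 (-3.67 ± 0.55), Cyp1b1, Bst1 and the Wnt antagonist gene Dkk2. Cpxm2 and Lrrc3b, at mean log2 CPM of -0.63 and -1.17, were called in 1 and 0 of the 3 edgeR fits with a library left out. Without the Plvap-led subcluster, an alternative chosen after seeing the data, the total of 1544 was 879, and the 5 genes named upward had no value. The same contrast in the controls, where no Cre is present, gave 1796 and 1722 genes, and 576 higher and 443 lower genes were common to both, where independent lists would share 110 and 110. Without iECKO 1 the total was 838. Undetected cells of the iECKO libraries were also shallower, with medians of 3522, 4027 and 4811 UMIs against 5275, 5903 and 6357.

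With capillary cells alone matched for depth, an alternative chosen after seeing the data, 76 genes were higher and 49 lower in undetected cells. Of these, 21 and 21 were also called in the unmatched contrast of the controls, where no Cre is present (independent lists would share 10.5 and 7.92). That contrast covered all endothelial cells, and 87.0% to 92.1% of its undetected cells lay in the Plvap-led subcluster, which was given no zone. Control 1 to 3 held 14, 20 and 2 undetected capillary cells, so what the gate selects among capillary cells could not be tested. The contrast over all endothelial cells of the controls had the same direction for Cx3cl1 (1.71), Rsad2 (1.29), Enpp2 (0.83), Efnb2 (2.08), Slc38a5 (-5.49) and Slc16a1 (-3.90). It had the opposite direction for Ifit2 (-0.66), Gbp2 (-0.78), Sema3g (-0.78), Hey1 (-1.67), Fos (0.70), Fosb (0.50) and Jun (0.32). In the matched iECKO cells fractalkine (Cx3cl1, 1.01 ± 0.10, adjusted p = 6e-10), Enpp2 (1.03 ± 0.11) and the interferon-induced genes Rsad2 (1.31 ± 0.14, adjusted p = 1.7e-08), Ifit2 (1.24 ± 0.21, adjusted p = 0.000138) and Gbp2 (0.78 ± 0.14, adjusted p = 0.000221) were higher. Without matching, Rsad2 and Ifit2 did not pass in capillary cells (adjusted p = 0.208 and 0.154) or over all endothelial cells (adjusted p = 0.121 and 0.361). Also higher with matching were the arterial genes Sema3g, Hey1 (0.95) and Efnb2 (0.92 ± 0.16, adjusted p = 0.000381). The immediate-early genes Fos (-0.80 ± 0.09, adjusted p = 3.27e-09), Fosb (-0.74 ± 0.11) and Jun (-0.51 ± 0.09, adjusted p = 0.000186) were lower. The amino acid transporter gene Slc38a5 (-0.60 ± 0.11, adjusted p = 0.000657), Slc16a1 (-0.42 ± 0.08, adjusted p = 0.0016) and Car4, a membrane carbonic anhydrase gene, were lower too. By list, 8 of 25 interferon-induced genes were higher over all genes and 15 adjusted over the list alone. Of 21 activation genes 5 (8 over the list alone) were higher. Of 27 immediate-early genes 6 (9) and of 25 transporters 4 (7) were lower. Angiogenesis genes had 2 higher over all genes and 5 higher and 2 lower adjusted over the list alone. An endothelial cluster led by Ifit2 held 170 of 5048, 155 of 1899 and 988 of 3037 endothelial barcodes of iECKO 1 to 3. In control 1 to 3 it held 227 of 4445, 129 of 4828 and 632 of 3127, so it was most frequent in replicate 3. In the unmatched fits with a library left out, Rsad2, Ifit2 and Gbp2 were called in 2, 1 and 3 of 3. The matched fit was not repeated with a library left out. The genes named here were chosen after their values were seen.

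The Cdh5 promoter directs Cre to endothelial cells, so the cells around them were asked after next, pericytes first. Timp3, an inhibitor of matrix metalloproteinases (ENSMUSG00000020044), rose from 283 ± 102 to 961 ± 351 CPM (1.74 ± 0.30, adjusted p = 0.00653). The chemokine gene Cxcl12 fell from 274 ± 19.2 to 105 ± 27.3 CPM (-1.43 ± 0.29, adjusted p = 0.0413). Both changes were seen in 3 of 3 pairs. With the block 10 genes rose and 3 fell. The basement membrane collagen gene Col4a1 (from 597 ± 120 to 1270 ± 532 CPM, 0.97 ± 0.20, adjusted p = 0.0299), Crispld2 (2.51 ± 0.52), Tcim (1.76 ± 0.39) and the mitochondrial gene mt-Co3 (0.67 ± 0.13) rose. Daam1 (-1.14 ± 0.23) and Ecm2 (-0.79 ± 0.18) fell. Basement membrane, matrix and integrin genes rose (median 0.29, 15 of 17 positive, adjusted p = 5.9e-05; adjusted p = 0.173 with an estimated correlation). Timp3 was past the threshold over all genes and 2 members passed adjusted over the list alone. Smooth muscle contractile genes rose (median 0.42, 9 of 10 positive, adjusted p = 0.000655; adjusted p = 0.173 with an estimated correlation). Without the block 0 members were called by edgeR over all genes or adjusted over the list alone, and Acta2 over all genes and 4 adjusted over the list alone were called with it. Pericyte barcodes with smooth muscle markers had not been removed as mixed, so admixture of smooth muscle cells was not tested apart from this. Pericyte identity genes fell (median -0.21, 10 of 13 negative, adjusted p = 0.0212; adjusted p = 0.544 with an estimated correlation). Vtn stood at 12700 and 9650 CPM (-0.43 ± 0.26), with 0 members past the threshold over all genes or, without the block, adjusted over the list alone. TGF-beta and BMP genes rose (median 0.24, 4 of 5 positive, adjusted p = 0.0428, adjusted p = 0.395 with an estimated correlation), Tgfb1 being past the threshold adjusted over the list alone. Immediate-early genes rose (median 0.33, 12 of 17 positive, adjusted p = 0.0197, adjusted p = 0.531 with an estimated correlation, 0.285 with the block), Egr1 adjusted over the list alone. The direction of this camera test was not the same in all fits with 1 library left out (largest adjusted p = 0.661). In those fits the largest camera adjusted p was 0.357 for pericyte identity and 0.187 for TGF-beta and BMP genes. It was 0.000976 for the matrix and 0.0478 for the contractile list. Activation (median 0.23, adjusted p = 0.16) and MHC class I genes (median 0.23, adjusted p = 0.17) did not pass. The sums held 39 to 79 control and 50 to 80 iECKO pericytes, and 152 of the 3109 genes tested had an unadjusted p under 0.05. DESeq2 called 1, and the total of 2 became 7 without control 1, 6 without iECKO 3, 1 without control 2 and 0 without control 3. With mixed barcodes kept, an alternative chosen after seeing the data, edgeR called 0 of 9147 genes (241 at an unadjusted p under 0.05), with Timp3 at 0.70 and Cxcl12 at -0.63.

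In smooth muscle cells Ifitm1, an interferon-induced membrane protein gene, rose from 8.93 ± 6.69 to 90.7 ± 43.4 CPM (3.36 ± 0.36, adjusted p = 2.31e-07). Dmp1, a matrix phosphoprotein gene, rose from 16.3 ± 5.89 to 47.1 ± 21.8 CPM (1.64 ± 0.32, adjusted p = 0.0197). The tubulin-binding gene Tppp3 fell from 87.6 ± 18.3 to 30.8 ± 17.9 CPM (-1.26 ± 0.26, adjusted p = 0.0368), each in 3 of 3 pairs. With the block 11 genes rose and 8 fell. The prothrombinase gene Fgl2 (2.51 ± 0.22, adjusted p = 4.51e-07), Rasl10b (2.03 ± 0.28) and the chemokine-receptor-like gene Ccrl2 (0.93 ± 0.21) rose. Hist1h2bc (-0.93 ± 0.19), Rnd3 (-0.70 ± 0.16) and Wtip (-0.60 ± 0.14) fell. Interferon-induced genes rose as a list (median 0.55, 3 of 5 positive, adjusted p = 0.0328, adjusted p = 0.395 with an estimated correlation). With 1 library left out, the largest camera adjusted p of this list was 0.276. Over all genes 0 members passed without the block and Ifitm3 (0.66 ± 0.14, adjusted p = 0.0075) with it, and 1 passed adjusted over the list alone. Contractile genes (-0.09, adjusted p = 0.483), pericyte identity genes (0.06, adjusted p = 0.387), MHC class I genes (0.18, adjusted p = 0.0762) and activation genes (0.14, adjusted p = 0.157) did not pass. Neither did basement membrane genes (0.02, adjusted p = 0.56), cell cycle genes (median -0.04, mean 0.08, adjusted p = 0.552), TGF-beta genes (median -0.05, mean -0.02, test upward, adjusted p = 0.861) and immediate-early genes (median 0.07, mean -0.01, test upward, adjusted p = 0.894). The sums held 85 to 109 control and 26 to 247 iECKO cells, 253 of the 6863 genes tested had an unadjusted p under 0.05, and DESeq2 called 1. The total of 3 was 19 without iECKO 3, 7 without iECKO 1 and 1 without control 2 or control 3.

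In microglia, the resident macrophages of the brain, 2 genes passed the threshold without pairing. Ccl12, a ligand of the monocyte receptor CCR2, rose from 113 ± 31.3 to 472 ± 130 CPM (2.10 ± 0.26, adjusted p = 3.03e-05). The urokinase receptor gene Plaur rose from 8.39 ± 1.44 to 51.8 ± 24.1 CPM (2.62 ± 0.47, adjusted p = 0.0114), both in 3 of 3 pairs. With the block 16 genes rose and 2 fell. Ccl4 rose from 1140 ± 424 to 3280 ± 1480 CPM (1.54 ± 0.16, adjusted p = 7.51e-07) and Ccl3 from 475 ± 204 to 1330 ± 563 CPM (1.53 ± 0.16, adjusted p = 9.83e-07). Myc (1.75 ± 0.37, adjusted p = 0.0334) rose and Lst1 (-0.80 ± 0.18, adjusted p = 0.0449) fell. Cytokines and chemokines rose as a list (median 0.95, 11 of 12 positive, adjusted p = 1.65e-11; adjusted p = 0.173 with an estimated correlation). Ccl12 passed over all genes and 6 members adjusted over the list alone. With the block Cxcl10 (3.30 ± 0.38) and Tnf (1.05 ± 0.23) passed too. Cell cycle genes rose (median 0.95, 6 of 6 positive, adjusted p = 2.78e-05; adjusted p = 0.173 with an estimated correlation). Over all genes 0 members passed and adjusted over the list alone 4, Stmn1 at 1.65 ± 0.47 and the helicase gene Mcm3 at 0.96 ± 0.38 among them. Genes of disease-associated microglia rose (median 0.25, 11 of 13 positive, adjusted p = 0.000654; adjusted p = 0.173 with an estimated correlation). The lipase gene Lpl was the 1 member past the threshold adjusted over the list alone, and it passed over all genes with the block (2.12 ± 0.45, adjusted p = 0.0359). Apoe stood at 0.28 ± 0.25. Homeostatic genes fell (median -0.28, 12 of 13 negative, adjusted p = 0.000655; adjusted p = 0.395 with an estimated correlation). The list had P2ry12 at -0.39 ± 0.21, Tmem119 at -0.25 ± 0.23 and Cx3cr1 at -0.32 ± 0.23, with 0 members called over all genes or, without the block, adjusted over the list alone.

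Interferon-induced genes rose in microglia too (median 0.47, 8 of 11 positive, adjusted p = 0.00411, adjusted p = 0.395 with an estimated correlation), with 0 members past the threshold over all genes in edgeR. Stat2 and Ifi27l2a were among those past it adjusted over the list alone. With 1 library left out, the largest camera adjusted p of this list was 0.0952. MHC class I genes did not pass (median -0.01, mean 0.27, adjusted p = 0.0934). They passed with the block (adjusted p = 0.0474; adjusted p = 0.536 with an estimated correlation), with H2-K1 (0.79 ± 0.17) and H2-Q7 (2.14 ± 0.43) past the threshold over all genes. MHC class II genes (0.01, adjusted p = 0.633) and immediate-early genes (-0.04, adjusted p = 0.794) did not pass. Mrc1, a marker of perivascular macrophages, stood at 3.09 ± 2.95 and 68.4 ± 91.5 CPM in these microglia sums. The sums held 109 to 149 control and 36 to 170 iECKO cells, 281 of the 6393 genes tested had an unadjusted p under 0.05, and DESeq2 called 1. The total of 2 was 13 without control 2, 6 without control 3 and 1 without control 1 or iECKO 1. Across the classes around the vessel 0 of 24 lists passed with an estimated correlation or with fry, against 11 with camera.

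**Figure D4:**
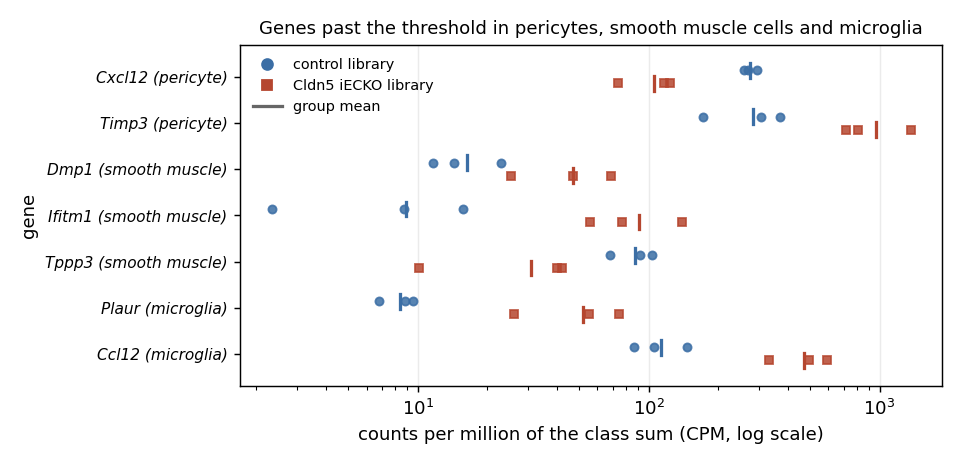
CPM in the class sum (x axis, log scale) for the genes past the threshold without pairing in pericytes, smooth muscle cells and microglia (y axis). Circles are control and squares Cldn5 iECKO libraries, 3 each, and vertical bars the group means. For each gene the iECKO libraries lie on 1 side of all controls, as for Ccl12 in microglia with means of 113 and 472 CPM.

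Lymphocytes were tested in 3 control and 2 iECKO libraries, since iECKO 2 held 7 of them. The class joined a B cell cluster and a T cell cluster that Ccl5 leads. Before mixed barcodes were removed these held 19, 16 and 54 B cells and 23, 16 and 17 T cells in control 1 to 3 and 21 and 35 B cells and 11 and 16 T cells in iECKO 1 and 3. The T cell and natural killer cell chemokine gene Ccl5 was 40.5 ± 56.3 CPM in the controls and 1280 ± 42.3 CPM in iECKO 1 and 3 (5.23 ± 0.93, adjusted p = 0.999). It passed the threshold with the block (5.20 ± 0.58, adjusted p = 0.000109), a fit that rests on 2 complete pairs. Without it edgeR called 0 genes, with 38 of 1776 at an unadjusted p under 0.05, and DESeq2 called 1. Counts without single libraries were 2 without control 1, 2 without control 3, 1 without iECKO 1, 1 without iECKO 3 and 0 without control 2. Without iECKO 1 or iECKO 3 a single iECKO library was left, so the controls alone gave the spread.

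The make-up of the suspension was compared last, although the PECAM1 beads set it. Endothelial cells made up 87.8% ± 2.55 of control and 85.8% ± 4.36 of iECKO cells (two-sided exact permutation p = 0.6). The exact test gave p = 0.6 for pericytes (1.32% ± 0.477 and 1.84% ± 0.735). Further shares were smooth muscle cells 2.19% ± 0.707 and 2.68% ± 1.53 (exact p = 0.7), microglia 2.75% ± 0.405 and 2.36% ± 0.616 (p = 0.5) and lymphocytes 0.962% ± 0.701 and 0.654% ± 0.44 (p = 0.6), with SD and n = 3. All adjusted p were 0.7, and the smallest p of this exact test is 0.1. Of the non-endothelial cells alone, microglia were 22.9% ± 3.29 in control and 16.8% ± 1.05 in iECKO libraries (exact p = 0.1, adjusted p = 0.4), lower in 3 of 3. The difference in endothelial share was 0.323 percentage points without iECKO 1 where it was -2.01 with it, that of smooth muscle -0.321 where it was 0.49, and that of lymphocytes 0.0845 without control 3 where it was -0.308.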

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

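The zone comparisons were planned; the alternatives on zone naming given here, and all splits of the samples, were tests chosen after the results were seen.

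The effect of genotype differed between zones by an interaction test, which is why these results stand here: 181 genes between venous and capillary cells and 13 between arterial and capillary cells. Venous cells had lower changes than capillary cells for the cytoskeletal gene Rhoc (capillary 1.49, venous 0.09) and the matrix gene Nid2 (1.69 and 0.14), and higher ones for the ferroxidase gene Cp (difference 1.02). Arterial cells had lower changes than capillary cells for Nrp1 (-0.90), a VEGF co-receptor gene, and the Notch ligand gene Dll4 (-0.80). Of the capillary cells of iECKO 1, most lay in the Apln-led subcluster, so its naming may account for part of the differences: counted as venous, it gave 1621 and 0 genes, with Rhoc at 0.99, Nid2 at 1.37 and Cp at -0.40, each reversed. Without iECKO 3 the counts were 442 and 182, without iECKO 1 the venous count was 45, without control 1 the counts were 53 and 4, without control 2 they were 71 and 8, without iECKO 2 they were 65 and 7, and without control 3 the venous count was 57. Among the 10 splits of the libraries, 1 gave as many genes in each comparison, the real split, and the highest other splits gave 5 and 2 genes. With 10 splits no share under 0.05 can be had.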

How the results depend on the processing

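Tests with mixed barcodes kept, with sex or Gm42418 as covariates, without both females, with the Apln-led or Plvap-led subclusters moved or left out, in capillary cells only, matched or drawn for cell number, with at least 5 Cldn5 UMIs and the block together, and with the block and an estimated correlation together were chosen after the results were seen; the others were planned. The cause of each shift below was not tested.

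The share of endothelial cells without a Cldn5 UMI stayed higher in iECKO libraries under every alternative run, with differences of 10.1 to 22.2 percentage points. Cldn5 in endothelial cells was -0.81 with DESeq2 and -0.80 with the replicate block, both past the threshold, and -0.87 (without iECKO 1) to -0.71 (without iECKO 2) with 1 library left out, its adjusted p ranging from 0.000145 to 1 over the alternatives.

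With DESeq2 133 genes were higher and 30 lower in endothelial cells, and 1 changed in pericytes, 1 in smooth muscle cells, 1 in microglia, 295 in capillary, 29 in arterial and 14 in venous cells, 23 between arterial and capillary changes, 652 within iECKO libraries and 162 in cells that kept Cldn5. With no filter on low counts the counts were 50 higher and 7 lower in endothelial cells, 13 in pericytes, 13 in smooth muscle cells, 16 in microglia, 114 in capillary, 137 in arterial and 91 in venous cells, 487 and 232 for the venous and arterial interactions, 61 in cells that kept Cldn5 and 743 in cells without it. With the replicate block they were 154 higher and 63 lower, 13 in pericytes, 19 in smooth muscle cells, 18 in microglia, 399 in capillary, 320 in arterial and 30 in venous cells, 227 in cells that kept Cldn5 (252 with at least 5 Cldn5 UMIs) and 1232 in cells without it. Without a block the interactions gave 0 and 0 genes and the contrast within iECKO libraries 154.

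Equal numbers of cells gave 4 higher and 2 lower endothelial genes and 1 gene in microglia. The marker gate gave 0 higher endothelial genes, as did keeping mixed barcodes, which also gave 0 in pericytes. RLE factors gave 2 genes in arterial cells and 3 in cells that kept Cldn5. Leaving out both females gave 0 higher endothelial genes, 5 in smooth muscle cells, 13 in microglia, 0 in capillary and 0 in arterial cells, 0 in cells that kept Cldn5 and 218 in cells without it. Sex as a covariate gave 0 higher endothelial genes, 5 in smooth muscle cells, 0 in capillary cells and 0 in cells that kept Cldn5. Counts of 0 here are from edgeR.

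Capillary cells without the Apln-led subcluster gave 0 genes and venous cells with it 551; counted as venous it gave 1621 and 0 interaction genes, with Bmx at -0.11, Cp at -0.40, Nid2 at 1.37, Litaf at 0.092 and Rhoc at 0.99, each reversed. Without the Plvap-led subcluster the contrast within iECKO libraries gave 879 genes and cells without Cldn5 against controls 117. In capillary cells only these were 767 and 131, and 3 for cells that kept Cldn5. The contrast within iECKO libraries gave 125 genes matched for depth and 541 with equal numbers drawn at random; Ch25h reversed to 0.34 in capillary cells only and 1.21 matched for depth. With all control cells as the reference the counts were 33 and 279 for cells with and without Cldn5.

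With 1 library left out, higher endothelial genes ranged from 0 (without any 1 of the controls, iECKO 1 or iECKO 2) to 102 (without iECKO 3) and lower ones from 0 to 12 (without iECKO 3). Pericytes ranged from 0 (without control 3) to 7 (without control 1), with 6 without iECKO 3 and 1 without control 2, smooth muscle cells from 1 (without control 2 or control 3) to 19 (without iECKO 3), with 7 without iECKO 1, and microglia from 1 (without control 1 or iECKO 1) to 13 (without control 2), with 6 without control 3. Capillary cells ranged from 0 (without control 2 or control 3) to 315 (without iECKO 3), with 1 without iECKO 2, 2 without control 1 and 7 without iECKO 1. Arterial cells ranged from 0 (without control 3 or iECKO 1) to 14 (without iECKO 3) and venous cells from 0 to 18 (without iECKO 3), with 2 without control 3. The venous interaction ranged from 45 (without iECKO 1) to 442 (without iECKO 3), with 53, 71 and 57 without control 1, control 2 and control 3 and 65 without iECKO 2. The arterial interaction ranged from 4 (without control 1) to 182 (without iECKO 3), with 8 without control 2 and 7 without iECKO 2. The contrast within iECKO libraries ranged from 838 (without iECKO 1) to 1256 (without iECKO 2). Cells that kept Cldn5 ranged from 0 (without control 2, control 3, iECKO 1 or iECKO 2) to 141 (without iECKO 3), with 2 without control 1, and cells without it from 217 (without control 3) to 478 (without iECKO 3), with 243 without iECKO 1.

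Differences in class shares ranged from -3.99 to 0.323 percentage points for endothelial cells (without iECKO 2 and iECKO 1), from -0.321 to 1.2 for smooth muscle cells (without iECKO 1 and iECKO 2) and from -0.59 to 0.0845 for lymphocytes (without control 2 and control 3). Smooth muscle cells stood at -0.012 with the stricter filter. Lists past the threshold in endothelial cells ranged from 5 (without control 2) to 9 with 6 without iECKO 1, and were 0 with an estimated correlation, 0 with fry and 0 with the block and an estimated correlation, as were the 0, 0 and 0 lists in the other classes. Lists whose test direction reversed with 1 library left out, and that passed the threshold with or without that library, were those of immediate-early genes in pericytes (medians from 0.003 without control 3 to 0.66 without control 2), smooth muscle cells (-0.19 without iECKO 1 and -0.14 without control 3 to 0.24 without control 2) and microglia (-0.26 without control 3 to 0.32 without control 2), and of MHC class II genes in microglia (-0.34 without control 3 to 0.43 without control 1). The pericyte test covered 3109 genes, 1763 with equal numbers of cells and 9147 with mixed barcodes kept, so the counts summed limit it. The stricter filter in pericytes was not run, since too few cells were left. Of the single genes and lists followed, 3 passed without the replicate block and not with it: Fscn1 in cells that kept Cldn5, Gkn3 in cells without it, and the immediate-early list in pericytes.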

Other observations

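All tests of explanations in this part were chosen after the results were seen.

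Why more endothelial calls appear with the replicate block could lie in a property that libraries of the same number share and that adds to the spread between libraries. The sex of the mice in place of the replicate number gave 0 genes past the threshold in edgeR (1222 at an unadjusted p under 0.05). The Gm42418 level of a library gave 1 (1133), against 960 at that p with neither. Neither alone gave the calls of the block. Either may be a part of what it removes, which these counts cannot exclude. The SE of Cldn5 was 0.127 with sex, 0.192 with Gm42418, 0.197 with neither and 0.09 with the block. A property shared within the pairs is the same in both groups and would not itself set them apart. A response to claudin-5 loss is a hypothesis, and Cre, which the iECKO mice alone carried, was not tested apart from it.

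Cells that kept Cldn5 differed from control cells with the replicate block. The fit of cells with at least 2 Cldn5 UMIs on their own called 227 genes, against 0 in the other splits that part every pair. The changes were thus not limited to cells without a Cldn5 UMI. Free Cldn5 RNA at the level seen in the microglia kept does not account for them. With at least 5 Cldn5 UMIs 252 genes were called, and 0 of 135, 26 and 69 microglia of iECKO 1 to 3 had that many (exact upper bounds 2.7%, 13.2% and 5.21%). Before this count 4.49%, 10.0% and 3.49% of their microglia barcodes had been removed as mixed, which may lower that level. Of the capillary cells of these libraries 49.3%, 24.6% and 6.82% had at least 5 and lay in the Apln-led subcluster. Deleted cells whose transcript is still counted would pass both gates, so a response limited to deleted cells is not excluded. Signals from neighbouring cells may play a part, and since Cldn5 was itself -0.64 in cells that kept it, partial loss within them may too. None of these was tested.

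Capillary cells without a Cldn5 UMI differed from detected capillary cells of the same library in some members of several lists. Matched for depth, in a fit not repeated with a library left out, 8 of 25 interferon-induced and 5 of 21 activation genes were higher. Of 27 immediate-early genes 6 and of 25 transporters 4 were lower. The depth of the cells does not account for all of it: 125 genes passed with cells matched for depth, and 541 with equal numbers drawn at random. A place nearer the arterial end may be part of it, as 68% of the 125 genes went the way arterial cells differ from capillary cells in the controls, against 45.7% of other genes. Among the interferon-induced genes past the threshold 8 of 8 did (median 0.35). This cannot be told apart from an effect of the deletion, because Cldn5 loss was itself more frequent in arterial cells. Swapping the classes within libraries gave at most 1 gene in the other 3 of 4 swaps, too few for a share under 0.05; 1 of these splits, the real one, gave as many.

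How often other splits of the same 6 libraries gave as many genes was counted. Of 10 splits, 1 gave as many in endothelial cells (real 1, highest other 0), capillary (4 and 0) and arterial cells (4 and 3), cells that kept Cldn5 (6 and 0) and cells without it (491 and 0). In pericytes 2 of the splits gave as many (real 2, highest other 7), in smooth muscle cells 3 (3 and 17), in microglia 3 (2 and 15) and in venous cells 10 (0 and 3). For the lists 3 splits gave as many in endothelial cells (9 and 10) and 2 in the other classes (11 and 14). The highest splits in pericytes, smooth muscle cells and microglia put control 1, control 3 and iECKO 3 together and called several times the real count. This split keeps both libraries of replicate 2 on 1 side and both of replicate 3 on the other. Differences between replicate numbers may therefore add to its counts, which was not tested. With the replicate block, 1 of the 4 splits that part every pair of libraries gave as many, the real one. Against the highest other split it gave 217 against 0 in endothelial cells, 13 against 1 in pericytes, 19 against 3 in smooth muscle cells and 18 against 8 in microglia. The counts were 399 against 0 in capillary, 320 against 0 in arterial and 30 against 0 in venous cells. Cells that kept Cldn5 had 227 against 0 and cells without it 1232 against 0. Within iECKO libraries, with the library as a block, undetected and detected cells were swapped in 4 ways. The real one gave 1544 genes and the others 0. Neither 10 nor 4 splits, nor 4 swaps, can give a share under 0.05.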
